A study of Mus musculus with 6 samples.

How the data were processed

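RNA was sequenced from the gastrocnemius of NSG mice bearing MDA-MB-231 tumours, in 3 control and 3 radiotherapy libraries, per the labels, which do not say whether each library came from a separate mouse. Libraries were made from total RNA with a TruSeq kit, per the labels' protocols. The deposited table holds TPM, transcript levels scaled by the authors for length and library size. The submitters' processing notes name HISAT2, StringTie and RSEM with no version, order or role. The notes name the mouse build mm9, while many identifiers in the table are newer than that build, so no positions are given. The annotation release is not given in the sources used here. The table lists 55995 features, of which 55414 have Ensembl identifiers, 581 are loci assembled without one and 29604 are at 0 in every library. The total TPM is the same in each library. No read counts were used, so the depth is unknown, no count test was made and no detection limit is given.

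Groups were taken from the labels. The comparisons, gene lists, rule for named genes and alternatives were fixed before the data were examined. Features with a mean of at least 1 TPM over the 6 libraries were tested, 11938 in all, of which 504 have no gene name. Values were log2(TPM + 1). Differences between radiotherapy and control were tested two-sided with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend), with no covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested features. The threshold was an adjusted p of 0.05. With 3 libraries against 3, an exact permutation test of a single gene cannot go below 0.1.

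Of 36 gene lists, 33 with at least 5 tested members were tested, 21 programme lists and 12 cell type marker lists, and 969 of 971 list entries were found in the table. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 33 lists. Camera compares a list with all other genes, so a list can be higher than other genes while its own median is below 0. For each list the number of members past the threshold was counted over all genes and adjusted over the list alone. With an estimated correlation in place of the preset, 0 of the 33 lists passed. Some genes are in more than 1 list, such as Gdf15, Eda2r and Cd36.

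The named genes were the 12 strongest in each direction that were separated between the groups and were not predicted models, filled up by the smallest unadjusted p where fewer passed, a fixed panel of fibrosis, polyamine, p53, atrophy and myosin genes, and up to 4 members with the smallest p of each list described by its members. Features without a gene name were left out of the strongest genes, a reading of the rule made after the data were examined. Lists described only by counts have no named members, and 1 gene that the rule names is not reported here. Log2 changes are radiotherapy minus control, and group values are the mean TPM ± SD with n = 3.

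The gene test was checked on simulated data with the means and spread of these libraries and 200 changed genes. At the observed spread it recovered 2.35% of genes changed by 1, 42.4% of genes changed by 2 and 66.4% of genes changed by 3 on the log2 scale, with 6.88% of calls false over 20 simulations. In the list test, a list shifted by 1 on the log2 scale was called in 20 of 20 simulations, with 3 calls of other lists. Other splits of the real libraries into 3 and 3 gave 9 to 23 list calls with the preset correlation. The low number of other calls in simulation may therefore not hold for these data. Figures were drawn with matplotlib 3.10.9.

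The alternatives were pseudocounts of 0.1 and 0.5, a mean of at least 5 TPM, no filter on low values, median-of-ratios scaling, rescaling without mitochondrial and the 20 most abundant genes, quantile normalisation, no trend, robust empirical Bayes, the replicate number as a block, and leaving out each library in turn. For lists, an estimated correlation, fry and ranks were added. Splits of the 6 libraries into 3 and 3, 10 in all with the real one, were also tested.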

Results

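Gene expression was measured by RNA-seq in the gastrocnemius, a calf muscle made mostly of fast-twitch fibres, of NSG mice, an immunodeficient strain that lacks mature T, B and NK cells. The mice carried tumours grown under the skin of the left flank from MDA-MB-231, a human breast cancer cell line. In the radiotherapy group the tumour was given 10 Gy of 6 MV X-rays at 6 Gy per minute once it measured about 800 mm3, and the gastrocnemius of the opposite side was taken 3 days later. The control group was not irradiated. Each group held 3 libraries, 6 in all. The labels do not say that the libraries of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The values are TPM, transcript levels scaled for transcript length and library size, with the same total in every library and no read counts, so the depth is unknown and the precision of each value rests on the spread between 3 libraries. The comparison asks which genes differ in muscle outside the beam after the tumour is irradiated. No tumour volume or day of collection is given for the control group. A difference in either between the groups could not be told apart from irradiation. The title of the study names muscle fibrosis and spermidine synthase, the enzyme that makes spermidine.

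Extracellular matrix genes lay higher on average in the radiotherapy muscles than in the control muscles, through partly different genes in radiotherapy replicate 3. The mean level of p53 response genes lay lower in all 3 radiotherapy libraries, while the mean levels of immediate early genes and of genes of muscle protein breakdown lay lower in radiotherapy replicates 1 and 2 and not in replicate 3. Jun, an immediate early transcription factor, fell from 84.4 ± 18.5 to 10.8 ± 1.52 TPM (SD, n = 3 per group). Radiotherapy replicate 3 stood apart from replicates 1 and 2 in many of these genes, with the highest levels of atrophy, acute-phase and neutrophil genes of all 6 libraries. Of 11938 genes tested with limma, 5 were higher and 2 lower at an adjusted p under 0.05, and 141 were higher and 1584 lower at an unadjusted p under 0.05. Over all tested genes, 206 were higher and 2299 lower in all 3 radiotherapy libraries than in every control library. A log2 change below 0 was found in 78.5% of them. The counts of list members given below are to be read beside these. Of 33 gene lists, 9 programme lists and 11 cell type lists passed with a preset correlation between genes, and 0 with an estimated correlation.

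Collagens and other matrix proteins made up the group with the strongest list test. Of 34 matrix and fibrosis genes tested, 11 were higher in all 3 radiotherapy libraries than in every control library. Above the median change of all genes, -0.36, lay 31 of them, and 7 had a log2 change below 0, beside 78.5% of all genes. Col3a1, a fibrillar collagen chain, was at 3.86 ± 0.416 TPM in control and 16.0 ± 6.69 TPM in radiotherapy muscle, a log2 difference of 1.71 (SE 0.37). Col1a1, the main chain of type I collagen, was at 1.81 ± 0.399 and 9.22 ± 5.64 TPM, and Col1a2, its partner chain, at 2.69 ± 0.957 and 9.93 ± 5.65 TPM. Postn, the matrix protein periostin, was at 1.17 ± 0.447 and 5.27 ± 2.69 TPM, and Fn1, fibronectin, at 4.07 ± 1.38 and 8.57 ± 1.08 TPM. The type VI collagen chains followed the same direction, with Col6a2 at 2.24 ± 0.127 and 6.46 ± 1.26 TPM. Col6a3 was at 1.94 to 2.57 TPM in the control and 3.71 to 7.07 TPM in the radiotherapy libraries. No member passed the test over all genes (0 of 34), and 2, Col3a1 and Col6a2, passed when adjusted over the list alone, both at an adjusted p of 0.0384. The list as a whole was higher by limma's camera test with a preset correlation (adjusted p = 3.50e-16, median log2 change 0.92 above that of all genes), and gave an adjusted p = 0.159 with an estimated correlation. In other splits of the 6 libraries into 3 and 3, limma's camera test with the preset also gave this list low unadjusted p-values, from 6.74e-07 to 0.0016. The exceptions were 0.2185 and 0.485, and the real split gave 1.06e-17. The mean log2 level of the list ran from 3.18 to 3.51 in the radiotherapy libraries and from 2.55 to 3.03 in the control libraries. Radiotherapy replicate 3 had the highest list mean of its group but the lowest levels of Col1a1 and Col3a1, with Col1a1 at 3.00 TPM against 10.7 and 14.0 TPM. Other members, named after their values were seen, were highest in it. In radiotherapy replicates 1, 2 and 3 Timp1 was at 4.24, 1.69 and 28.6 TPM, Lox at 1.64, 1.27 and 21.95 TPM and Col4a2 at 20.5, 20.2 and 87.0 TPM. In control they were at 1.99 to 3.55, 1.53 to 2.93 and 17.8 to 29.1 TPM. Tendon markers followed the same libraries as Col1a1 and Col3a1, with a mean log2 level of 3.59, 2.95 and 2.01 in radiotherapy replicates 1, 2 and 3 against 1.43 to 2.40 in control, and Fmod, a tendon proteoglycan, at 15.7, 13.9 and 0.32 TPM. Without replicate 3, 8 matrix genes passed over all genes, with Col1a1 at a log2 change of 2.25 in place of 1.67.

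**Figure D1:**
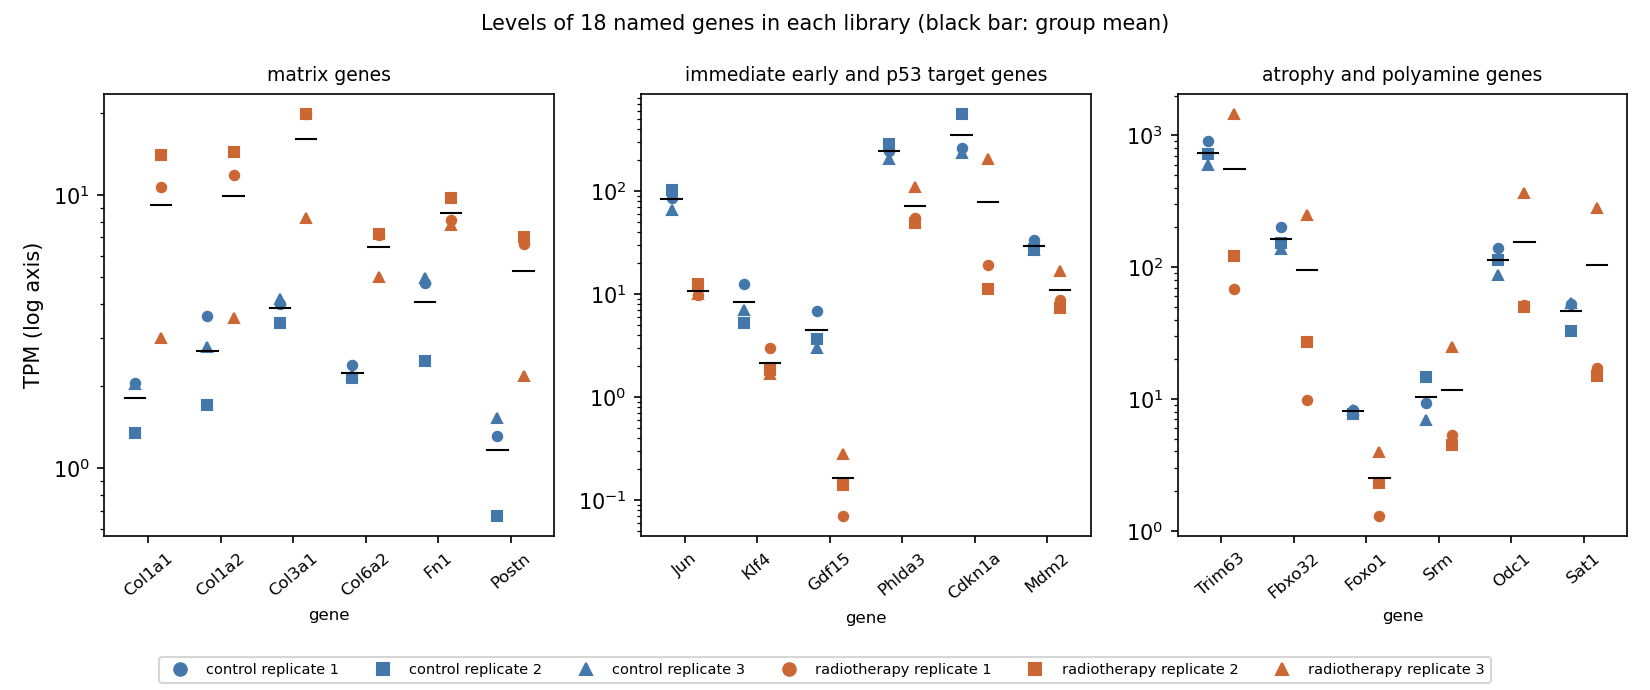
TPM of 18 named genes in each of the 6 libraries on a log axis, with control in blue, radiotherapy in orange and a black bar at each group mean. Col1a1, Col3a1, Col6a2, Fn1 and Postn were higher in all 3 radiotherapy libraries than in any control library, and Trim63 was at 68.8 and 122 TPM in radiotherapy replicates 1 and 2 and at 1462 TPM in replicate 3. The directions of Srm, Odc1 and Sat1 differ between scalings.

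TGF-beta signalling genes, which act upstream of matrix production, showed no shift of the list. Of 30 tested, 0 passed over all genes and 0 when adjusted over the list alone, and the list gave an adjusted p of 0.42. Without radiotherapy replicate 3, 7 members passed as lower and 1 as higher, beside 3298 and 236 of all 11938 genes. The list then gave an adjusted p of 0.793 by camera. Of its members, 4 were lower in all 3 radiotherapy libraries and 0 higher, beside 2299 and 206 of all 11938 genes. Acvr2a, an activin receptor, was at 4.80 to 6.13 TPM in control and 1.58 to 3.00 TPM in radiotherapy muscle. Tgfbr3, a TGF-beta co-receptor, was at 2.32 to 4.68 and 1.21 to 1.91 TPM, and Smad4, the shared SMAD partner, at 18.1 to 27.3 and 6.08 to 17.1 TPM. Mstn, which encodes myostatin and restrains muscle growth, was at 17.6 ± 6.71 and 7.22 ± 3.11 TPM. Tgfb1 was at 4.68 ± 0.524 and 5.51 ± 4.58 TPM, with a log2 change of -0.01 that became 0.35 with median-of-ratios scaling. Ccn2, a matrix-associated growth factor, was at 4.89 ± 3.05 and 11.6 ± 14.2 TPM, with 28.0 TPM in radiotherapy replicate 3, without which its log2 change went from 0.64 to -0.27. Acta2, smooth muscle actin, was at 35.4 ± 10.7 and 54.1 ± 12.7 TPM.

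Polyamine genes did not move as a list. Of 21 tested, 0 passed over all genes and 0 when adjusted over the list alone, and the list gave an adjusted p of 0.67. Srm, spermidine synthase, was at 10.3 ± 3.92 TPM in control and 11.6 ± 11.6 TPM in radiotherapy muscle. The group means hid a split, since Srm was at 5.36 and 4.47 TPM in radiotherapy replicates 1 and 2 and at 25.0 TPM in replicate 3. Odc1, the enzyme that makes putrescine, was at 51.7, 49.6 and 365 TPM in the radiotherapy libraries against 114 ± 25.6 TPM in control. Sat1, the enzyme that acetylates spermidine and spermine, was at 17.1, 14.8 and 280 TPM against 46.4 ± 11.8 TPM. The log2 changes of Srm, Odc1 and Sat1 were -0.17, -0.18 and -0.10 as deposited and 0.24, 0.28 and 0.35 with median-of-ratios scaling. Without radiotherapy replicate 3 they were -0.88, -1.12 and -1.45, and those of Odc1 and Sat1 then passed over all genes (adjusted p = 0.0235 and 0.0193), while Srm did not (0.0819). In that setting 236 genes passed as higher and 3298 as lower, and the median log2 change of all genes was -0.57. The polyamine list then gave an adjusted p of 0.29 by camera, with a median of -0.066 relative to all genes. Sms, spermine synthase, was lower in all 3 radiotherapy libraries, at 49.8 ± 11.9 and 29.3 ± 3.91 TPM, and Mat2b, a methionine adenosyltransferase subunit, at 31.1 ± 3.11 and 16.8 ± 2.26 TPM. Smox, spermine oxidase, was at 23.7 ± 8.38 and 28.8 ± 9.30 TPM. Paox, which oxidises acetylated polyamines, was at 8.48 to 85.3 TPM in the control and 1.28 to 28.9 TPM in the radiotherapy libraries. Atp13a3, a polyamine transporter, was at 2.01 to 3.54 and 0.66 to 2.20 TPM.

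Targets of p53 were lower in the radiotherapy muscles. Of 29 tested, 15 were lower in all 3 radiotherapy libraries than in every control library and 0 were higher. No member passed over all genes (0 of 29), and 12 passed as lower when adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, was at 355 ± 184 TPM in control and 79.0 ± 111 TPM in radiotherapy muscle. Mdm2, the p53 ubiquitin ligase, was at 29.3 ± 3.96 and 10.9 ± 5.04 TPM. Gdf15, a stress-induced cytokine linked to appetite loss, was at 4.48 ± 2.04 and 0.163 ± 0.107 TPM, and Eda2r, a TNF receptor family member, at 14.7 ± 4.69 and 2.28 ± 1.66 TPM. Phlda3 was at 246 ± 41.6 and 71.2 ± 33.5 TPM and Dcxr at 45.8 ± 24.9 and 8.77 ± 2.56 TPM. The list was lower by camera (adjusted p = 6.71e-06, median log2 change -0.60 relative to all genes), with an adjusted p = 0.752 with an estimated correlation. Without radiotherapy replicate 3, in which Cdkn1a was at 207 TPM against 11.2 TPM in radiotherapy replicate 2, 16 members passed as lower and 1 as higher over all genes.

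Immediate early genes were lower as a list, at a mean log2 level of 2.26 and 2.22 in radiotherapy replicates 1 and 2, while replicate 3, at 4.31, lay inside the control range of 3.67 to 4.66. Of 22 tested, 6 were lower in all 3 radiotherapy libraries, 1 (Jun) passed over all genes and 2 (Jun and Klf4) passed when adjusted over the list alone. Jun had a log2 change of -2.85 (SE 0.28, adjusted p = 0.0329), -2.49 relative to the median of all genes. Klf4, a zinc finger transcription factor, was at 8.31 ± 3.87 TPM in control and 2.15 ± 0.720 TPM in radiotherapy muscle. Fos, the partner of Jun in AP-1, was at 29.5 to 82.3 TPM in control and at 0.77, 1.29 and 31.6 TPM in radiotherapy replicates 1, 2 and 3, and Fosb at 0.64 to 3.31 TPM in control and at most 0.25 TPM in radiotherapy muscle. The list gave an adjusted p = 0.00321 with the preset and an adjusted p = 0.79 with an estimated correlation, and without radiotherapy replicate 3 its members past the threshold went from 1 to 17. The call of Jun ended without control replicate 1, 2 or 3 (adjusted p = 0.247, 0.0938 and 0.0836) and without radiotherapy replicate 1 or 2 (0.252 and 0.146), with median-of-ratios scaling (0.143), with quantile normalisation (0.109) and without a filter on low values (0.0759), while its log2 change stayed between -3.02 and -2.39 over all settings tried.

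Genes of muscle protein breakdown, the ubiquitin and autophagy genes of muscle atrophy, were lower as a list through radiotherapy replicates 1 and 2, at a mean log2 level of 4.55 and 4.81, while replicate 3, at 6.84, lay above the control range of 6.29 to 6.54. All 38 tested members had a log2 change below 0, beside 78.5% of all genes. In all 3 radiotherapy libraries 9 were lower, beside 2299 of all 11938 genes. Over all genes 0 members passed, and 3 passed when adjusted over the list alone. These 3 were Eda2r, Foxo1, a transcription factor that drives atrophy genes, at 8.06 ± 0.339 and 2.53 ± 1.34 TPM, and Tnfrsf12a, the TWEAK receptor, at 196 ± 82.8 and 33.2 ± 24.7 TPM. Ube4a was at 14.5 to 18.7 TPM in control and 3.00, 3.26 and 10.4 TPM in the radiotherapy libraries. The muscle ubiquitin ligases Trim63 and Fbxo32 were at 598 to 901 and 137 to 202 TPM in control. In radiotherapy replicates 1, 2 and 3 Trim63 was at 68.8, 122 and 1462 TPM and Fbxo32 at 9.89, 27.0 and 248 TPM, so replicate 3 lay above every control library and the other replicates below. The list gave an adjusted p = 0.00456 with the preset and 0.823 as the adjusted p with an estimated correlation. Its call ended without control replicate 2 (adjusted p = 0.0795) or radiotherapy replicate 1 (0.112), and without radiotherapy replicate 3 the members past the threshold went from 0 to 27.

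Glucocorticoid-responsive and heat-shock genes were lower as lists in radiotherapy replicates 1 and 2 and not in replicate 3. The mean log2 level of the glucocorticoid list was 4.36, 4.69 and 6.80 in radiotherapy replicates 1, 2 and 3 and 6.12 to 6.41 in control, and that of the heat-shock list 5.18, 5.01 and 6.47 against 6.13 to 6.51. Mt1, a metallothionein, and Lcn2, lipocalin 2, members of the glucocorticoid list named after their values were seen, were at 14766 and 4327 TPM in replicate 3, above every control library. Of 24 glucocorticoid-responsive genes tested, 7 were lower in all 3 radiotherapy libraries, 0 passed over all genes and 1 passed when adjusted over the list alone, Pik3r1, a regulatory subunit of PI3-kinase, at 11.7 ± 1.84 and 2.48 ± 0.907 TPM. Klf9 was at 29.2 ± 7.34 and 14.3 ± 1.10 TPM and Glul, glutamine synthetase, at 389 to 802 and 109 to 365 TPM. Of 22 heat-shock genes, 5 were lower in all 3, beside 2299 of all 11938 genes. Over all genes 0 of them passed, and 4 passed when adjusted over the list alone. These were the inducible chaperones Hspa1a and Hspa1b, at 3.83 ± 1.45 and 0.843 ± 0.150 TPM and at 9.94 ± 3.89 and 2.34 ± 0.429 TPM, with the co-chaperones Chordc1 and Dnajb4, at 10.6 ± 0.814 and 3.67 ± 1.65 TPM and at 28.6 ± 1.90 and 11.2 ± 4.82 TPM. Both lists passed narrowly with the preset (adjusted p = 0.0473 and 0.0422) and gave an adjusted p = 0.823 with an estimated correlation. Without single libraries the glucocorticoid list lost its call in 5 of 6 cases, keeping it only without radiotherapy replicate 3 (adjusted p = 8.02e-04), with 0.0893, 0.0834 and 0.18 without control replicates 1, 2 and 3 and 0.397 and 0.107 without radiotherapy replicates 1 and 2. It also lost its call with pseudocounts of 0.1 (0.0528) and 0.5 (0.0512) and with a mean of at least 5 TPM (0.147). The heat-shock list lost its call with a mean of at least 5 TPM (0.177) and without control replicate 2 (0.366), radiotherapy replicate 1 (0.115) or radiotherapy replicate 2 (0.203). Without radiotherapy replicate 3, 15 glucocorticoid-responsive and 16 heat-shock members passed as lower over all genes, beside 3298 of all 11938 genes.

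Interferon-response genes were lower as a list, and inflammatory genes were not. The mean log2 level of the interferon list was 1.62, 1.68 and 1.86 in radiotherapy replicates 1, 2 and 3 and 1.75 to 3.89 in control. Of 36 interferon genes tested, 11 were lower in all 3 radiotherapy libraries, 0 passed over all genes and 0 when adjusted over the list alone. Control replicate 1 held the highest levels, with Isg15, a ubiquitin-like interferon-induced protein, at 63.2, 30.5 and 4.56 TPM in the 3 controls and 2.96 to 3.52 TPM in the radiotherapy libraries. Ifit3 was at 44.0, 16.1 and 1.86 TPM and at 0.31 to 2.46 TPM, Gbp2 at 3.04 to 15.3 and 1.45 to 2.08 TPM and Irgm1 at 8.74 to 17.7 and 2.95 to 4.78 TPM. The interferon list gave an adjusted p = 0.00954 with the preset and an adjusted p = 0.823 with an estimated correlation, 0.197 with a mean of at least 5 TPM, 0.233 without control replicate 1 and 0.955 without radiotherapy replicate 3. In that last setting its test direction relative to other genes turned to higher, while its median stayed at -0.45 relative to all genes. Of 37 inflammatory and acute-phase genes, 3 were lower in all 3 radiotherapy libraries, 0 passed over all genes and 0 when adjusted over the list alone, and the list gave an adjusted p of 0.67, with a median below that of all genes and a test direction above it. Lower in all 3 were Cxcl9, a chemokine induced by interferon-gamma, at 0.95 to 11.1 and 0.09 to 0.62 TPM, Irf1 at 6.29 to 20.9 and 3.38 to 4.89 TPM and Vcam1 at 1.53 to 7.85 and 0.51 to 0.88 TPM. Il6ra, the interleukin-6 receptor, was at 3.99 to 8.43 TPM in control and 0.27, 0.81 and 6.24 TPM in radiotherapy replicates 1, 2 and 3. Without replicate 3 the inflammatory list was lower (adjusted p = 7.70e-04).

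Genes of fatty acid oxidation were lower and mitochondrially encoded genes higher than other genes as lists. Of 36 fatty acid oxidation and PPAR target genes, 16 were lower in all 3 radiotherapy libraries, 0 passed over all genes and 3 passed when adjusted over the list alone. These were Cpt1b, the muscle carnitine palmitoyltransferase, at 94.5 ± 2.49 and 41.8 ± 3.99 TPM, Mlycd, malonyl-CoA decarboxylase, at 90.4 ± 17.9 and 34.5 ± 8.86 TPM, and Etfa, an electron transfer flavoprotein subunit, at 138 ± 18.4 and 56.4 ± 15.0 TPM. Etfdh was at 30.0 to 47.1 and 16.6 to 20.9 TPM. Without radiotherapy replicate 3, 12 members of the list passed as lower over all genes, beside 3298 of all 11938 genes. The list gave an adjusted p = 0.0473 with the preset, an adjusted p = 0.79 with an estimated correlation, 0.0606 and 0.0517 with pseudocounts of 0.1 and 0.5, 0.159 with a mean of at least 5 TPM, 0.14 with median-of-ratios scaling, 0.157 with rescaling, 0.184 with quantile normalisation, 0.394 without control replicate 3, 0.0961 without radiotherapy replicate 1 and 0.795 without radiotherapy replicate 3. Of 13 mitochondrially encoded respiratory chain genes, 12 lay above the median change of all genes, 1 was higher in all 3 radiotherapy libraries, mt-Nd3, at 1523 to 2184 and 2334 to 3134 TPM, and 0 passed over all genes or when adjusted over the list alone. mt-Nd1 was at 6018 to 11632 and 8348 to 15974 TPM and mt-Nd4l at 763 to 1117 and 918 to 1873 TPM. mt-Co3 was listed at 0.17 to 0.21 TPM in 5 libraries and at 269 TPM in control replicate 3, far below the other mitochondrial genes in every library, so its values may not measure expression. With mt-Co3 counted, the mitochondrial list was at a mean log2 level of 11.6, 11.6 and 10.8 in radiotherapy replicates 1, 2 and 3. Control replicates 1, 2 and 3 were at 11.3, 10.4 and 11.9. The mean of control replicate 3 is raised by its mt-Co3 value, so the overlap of replicates 1 and 2 with the control range may rest on that value. The list, also with mt-Co3, gave an adjusted p = 4.20e-06 by camera with the preset, an adjusted p = 0.79 with an estimated correlation and 0.223 with quantile normalisation. Of 32 glycolysis and glycogen genes, 1 was higher and 6 lower in all 3 radiotherapy libraries, beside 206 and 2299 of all 11938 genes. Of these 32, 0 passed over all genes or when adjusted over the list alone, and the list gave an adjusted p of 0.0817. Pfkfb3, which makes the activator of phosphofructokinase, was at 8.42 to 23.4 and 25.6 to 73.3 TPM. Ppp1r3a, a glycogen-targeting phosphatase subunit, was at 19.7 to 29.9 and 8.31 to 10.2 TPM, and Gbe1, the glycogen branching enzyme, at 30.8 to 45.9 and 8.90 to 26.9 TPM. Without radiotherapy replicate 3 the glycolysis list was higher than other genes by camera (adjusted p = 5.73e-04), but not higher than in control. Its mean log2 level was 7.475 and 7.419 in radiotherapy replicates 1 and 2 and 7.475 to 7.717 in control. In that setting 3 members passed as higher and 7 as lower over all genes, beside 236 and 3298 of all 11938 genes.

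The denervation and regeneration list did not move as a whole. Of 20 tested, 3 were lower and 1 higher in all 3 radiotherapy libraries, 0 passed over all genes and 2 passed when adjusted over the list alone. These were the muscle transcription factors Myog, at 30.9 ± 21.2 and 3.01 ± 0.836 TPM, and Myod1, at 33.6 ± 29.1 and 2.35 ± 1.82 TPM. Another muscle transcription factor of the list, Myf6, named after its values were seen, was at 217 to 433 TPM in control and at 49.0, 61.1 and 663 TPM in radiotherapy replicates 1, 2 and 3. Igf1, a muscle growth factor, was at 2.63 ± 1.02 and 5.70 ± 1.13 TPM, and the imprinted RNA H19 at 343 to 536 and 114 to 326 TPM. The list gave an adjusted p of 0.67, with a median 0.23 below that of all genes on the log2 scale and a test direction above it. Clock genes gave an adjusted p of 0.67, with 0 of 19 past the threshold over all genes and 0 when adjusted over the list alone. Arntl, the BMAL1 gene, was at 7.97 to 23.0 TPM in control and 0.86 to 5.04 TPM in radiotherapy muscle, Cry1 at 5.05 to 8.83 and 2.14 to 3.84 TPM, Csnk1e at 19.2 to 34.6 and 6.86 to 17.4 TPM and Cry2 at 11.4 to 21.2 and 4.32 to 14.0 TPM. The other lists that did not pass were the unfolded protein response (31 tested, adjusted p = 0.248, 1 adjusted over the list alone, which was Gdf15), cell cycle genes (14 tested, 0.42), lipogenesis (23 tested, 0.42), nuclear-encoded oxidative phosphorylation (56 tested, 0.67), ribosomal proteins (49 tested, 0.67, with a median above and a test direction below all genes) and oxidative stress genes (29 tested, 0.813). Relative to other genes, nuclear-encoded oxidative phosphorylation was higher with median-of-ratios scaling (0.0205) and with rescaling without mitochondrial and top genes (0.0332), and ribosomal proteins lower with quantile normalisation (0.0455). Each of these lists had 0 members past the threshold over all genes and, apart from Gdf15, 0 when adjusted over the list alone. Without radiotherapy replicate 3, nuclear-encoded oxidative phosphorylation was higher than other genes (8.42e-06), and ribosomal proteins and oxidative stress genes lower (0.025 and 0.0365). The mean log2 level of nuclear-encoded oxidative phosphorylation was 8.97 and 8.91 in radiotherapy replicates 1 and 2, inside the control range of 8.87 to 9.06. Without radiotherapy replicate 1 or 2 the unfolded protein response was higher than other genes (0.0373 and 0.0384).

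The mean levels of tendon and fast-fibre markers lay above every control library in radiotherapy replicates 1 and 2 and not in replicate 3. The mean log2 level of fast-fibre genes was 12.8 in both and 11.6 in replicate 3, against 12.1 to 12.2 in control, and that of progenitor markers was 3.84, 3.94 and 3.42 against 3.37 to 3.91. The tendon, fast-fibre and progenitor lists passed with the preset and gave an adjusted p = 0.752, 0.79 and 0.79 with an estimated correlation. All 6 tendon markers tested lay above 0, with Fmod at 1.26 to 3.92 TPM in control and at 15.7, 13.9 and 0.32 TPM in radiotherapy replicates 1, 2 and 3. Thbs4, a tendon matrix protein, was at 2.13 to 6.84 TPM and at 19.4, 15.2 and 3.60 TPM, Cilp at 0.750 ± 0.334 and 2.44 ± 1.98 TPM, and Col11a2 at 0.18 to 1.04 TPM and at 3.21, 2.85 and 0.57 TPM. Fibro-adipogenic progenitor markers, none of which passed, differed in direction, with Pi16 at 2.70 to 5.06 and 6.58 to 9.69 TPM, Serpinf1 at 7.06 to 16.6 and 11.6 to 46.6 TPM, Ly6a at 141 to 288 and 85.2 to 90.8 TPM, and Apod at 63.9 to 101 and 47.8 to 55.6 TPM. Among endothelial markers Vwf, von Willebrand factor, was at 9.35 to 17.1 and 26.5 to 29.6 TPM, while Cd36, Tek and Pecam1 were at 41.6 to 100.4, 3.55 to 4.48 and 28.8 to 37.8 TPM in control and 17.9 to 41.0, 1.88 to 2.57 and 15.7 to 35.0 TPM in radiotherapy muscle. Among pericyte and smooth muscle markers Tagln and Higd1b were at 22.7 to 33.7 and 38.0 to 48.8 TPM and at 2.61 ± 0.282 and 4.16 ± 0.385 TPM, and Abcc9 at 11.5 to 17.5 and 4.58 to 6.28 TPM. Fast-fibre genes gave Pvalb, the calcium buffer of fast fibres, at 3232 to 4522 TPM in control and 12653, 14462 and 2591 TPM in radiotherapy replicates 1, 2 and 3, Casq1 at 190 to 233 TPM and 1802, 1653 and 50.6 TPM, Tnnc2 at 17742 to 20408 TPM and 34214, 33248 and 16158 TPM, and Mybpc2 at 1786 to 1931 and 1136 to 1229 TPM. The fast myosin Myh4 was at 5059 ± 651 and 5464 ± 1272 TPM, and the slow myosin Myh7 at 8.61 to 251 and 32.5 to 362 TPM, with a log2 change of 0.09 for Myh4 that became -0.34 with quantile normalisation.

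By limma's camera test with the preset correlation, 11 of 12 cell type marker lists were higher than other genes. No marker passed over all genes, and 1, Abcc9, passed as lower when adjusted over the list alone. The adjusted p with the preset and then with an estimated correlation was 3.20e-05 and 0.752 for tendon (6 tested), 0.00218 and 0.752 for erythroid (7), 0.00186 and 0.79 for slow-fibre (17), 0.00218 and 0.79 for adipocyte (16), 0.00321 and 0.79 for fast-fibre (13), 0.00341 and 0.79 for neutrophil (12), 0.00954 and 0.79 for Schwann cell (10), 0.0101 and 0.79 for pericyte (15), 0.0124 and 0.79 for progenitor (19), 0.0432 and 0.823 for macrophage (26) and 0.0473 and 0.79 for endothelial markers (21). Satellite cell markers gave 0.344 and 0.823 (7 tested). Relative to all genes the median was highest for tendon (1.23), erythroid (1.01) and neutrophil markers (0.73) and slow-fibre genes (0.73), and the medians of the pericyte, progenitor, macrophage and endothelial lists were below 0 before the shift of all genes was taken off. Without radiotherapy replicate 3 the neutrophil list turned to lower (adjusted p = 0.0588) and the macrophage and endothelial calls ended (0.244 and 0.29). Without control replicate 2 the slow-fibre (0.708), macrophage (0.905), adipocyte (0.212), progenitor (0.271), endothelial (0.219) and Schwann (0.308) calls ended, and the slow-fibre and macrophage directions turned. Without control replicate 1 the endothelial call ended (0.0989). Without radiotherapy replicate 1 the fast-fibre (0.17), progenitor (0.112), pericyte (0.267), adipocyte (0.109), endothelial (0.0569) and Schwann (0.242) calls ended, and without radiotherapy replicate 2 the fast-fibre (0.228), slow-fibre (0.137), progenitor (0.303), macrophage (0.137) and Schwann (0.484) calls. Median-of-ratios scaling ended the slow-fibre (0.109), Schwann (0.123), macrophage (0.418) and neutrophil (0.428) calls, and quantile normalisation ended these and the erythroid (0.0644) and fast-fibre (0.611) calls, turning the fast-fibre direction. Rescaling without mitochondrial and top genes ended the fast-fibre (0.0945), macrophage (0.109) and neutrophil (0.081) calls, a mean of at least 5 TPM the macrophage (0.0629) and neutrophil (0.137) calls, a pseudocount of 0.1 the neutrophil call (0.0526) and ranks the endothelial call (0.076). Without a filter on low values the fast-fibre (0.0521), slow-fibre (0.0635), erythroid (0.0597), Schwann (0.069), progenitor (0.119), pericyte (0.122), endothelial (0.572) and macrophage (0.572) calls ended. The fibro-adipogenic progenitor list had a mean log2 change above 0 (0.02) and a median below 0 (-0.14). Lists for lymphocytes, keratinocytes and bone were not tested in the main setting, with 1, 2 and 2 members above the filter.

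**Figure D2:**
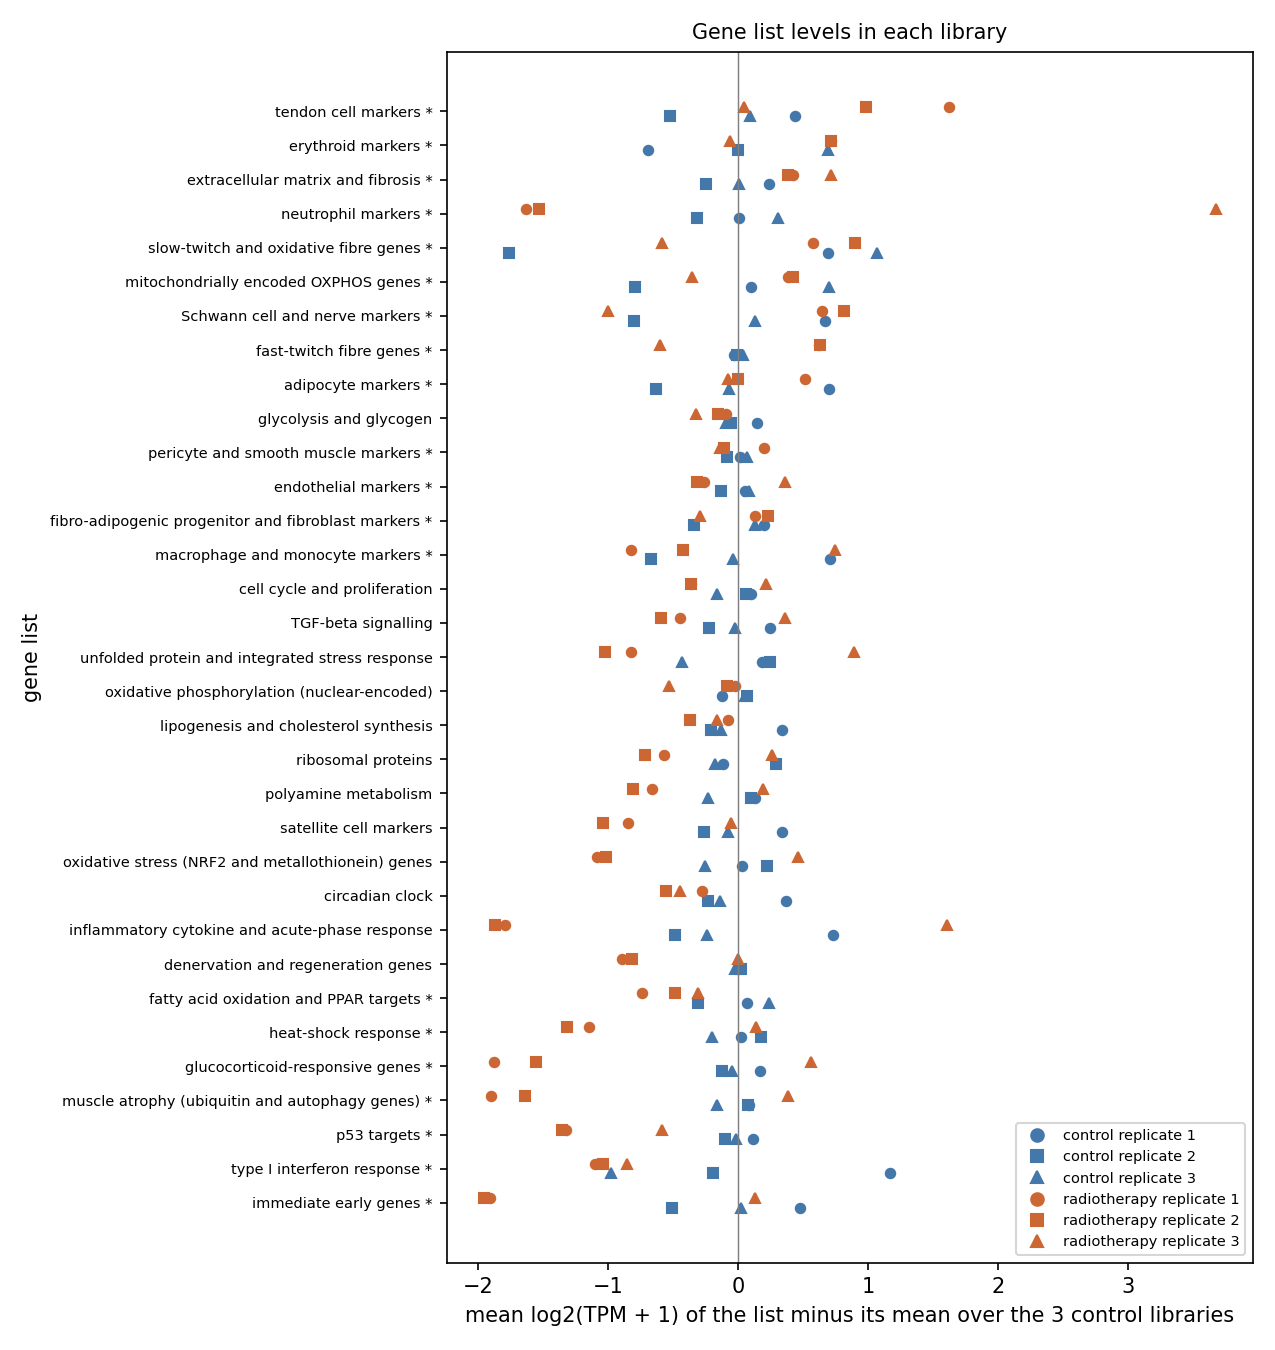
Mean log2(TPM + 1) of each of the 33 gene lists in each library, minus its mean over the 3 control libraries, ordered by median change, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The mean level of matrix genes lay above, and that of p53 targets below, every control library in all 3 radiotherapy libraries. Which matrix genes were highest differed between radiotherapy replicate 3 and replicates 1 and 2. Replicate 3 lay apart from replicates 1 and 2 in neutrophil, inflammatory, atrophy and fast-fibre genes.

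The genes with the strongest single tests were few and mostly listed at 0 in a whole group. Whether a listed 0 means no transcript or reads not assigned to the feature is not given in the sources used here, so these calls may not measure expression. Higher in radiotherapy muscle were Gm37375 (adjusted p = 0.00756), Gm37376, Gm22068 and Rnu1a1 (each 0.00917) and an Ensembl gene without a name, ENSMUSG00002075511 (0.0118), and lower were Gm25291 (0.00756) and Jun. Apart from Rnu1a1 and Jun these lie outside the rule for named genes, and they are named after their values were seen because they make up the count. Gm37375 was listed at 0 in all 3 controls and at 14.2, 25.5 and 26.3 TPM in radiotherapy muscle, and Gm25291 at 10.0, 14.4 and 11.3 TPM in control and 0 in all 3 radiotherapy libraries. Rnu1a1, a U1 small nuclear RNA gene, and Gm22068 had the same values, 0 in all controls and 56.1, 78.6 and 23.4 TPM, so their reads are not told apart. Rescaling without mitochondrial and the 20 most abundant genes gave 5 higher and 4 lower genes, a share of 55.6% higher in place of 71.4%. The counts of higher and lower genes were 0 and 4, 1 and 12 and 0 and 1 without control replicates 1, 2 and 3, and 3 and 0, 8 and 1 and 236 and 3298 without radiotherapy replicates 1, 2 and 3.

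Among named genes that did not pass over all genes but were higher in all 3 radiotherapy libraries, with adjusted p values of 0.238 to 0.264, were Thy1, a fibroblast and nerve surface protein (1.07 ± 0.0964 and 5.43 ± 1.98 TPM), Cntfr, the receptor for ciliary neurotrophic factor (2.07 ± 0.390 and 6.43 ± 1.33 TPM), and Tpsb2, a mast cell tryptase (0.427 ± 0.307 and 2.55 ± 0.299 TPM). Dupd1, a muscle dual-specificity phosphatase, was at 5.52 ± 0.501 and 24.6 ± 10.8 TPM, Hhatl at 20.7 ± 4.06 and 49.5 ± 3.99 TPM, Wfdc1 at 30.2 ± 3.29 and 76.9 ± 22.2 TPM, and Lsp1, a leukocyte protein, at 16.2 ± 4.53 and 36.8 ± 1.65 TPM. Cpxm1 was at 0.993 ± 0.0586 and 3.19 ± 0.0693 TPM, and Pla2g7, a phospholipase that degrades platelet-activating factor, at 5.93 ± 2.18 and 15.6 ± 2.83 TPM. Lower in all 3 radiotherapy libraries, with adjusted p values of 0.0831 to 0.183, were the histone genes H4c9 (126 ± 13.9 and 29.1 ± 2.31 TPM), H4c8 (186 ± 53.5 and 47.2 ± 2.95 TPM) and H2bc6 (15.0 ± 2.80 and 4.22 ± 0.0608 TPM). Fam13c was at 8.34 ± 1.03 and 1.19 ± 0.730 TPM, Car2, carbonic anhydrase 2, at 9.84 ± 1.28 and 2.54 ± 0.204 TPM, Myo18a at 101 ± 23.8 and 26.9 ± 3.61 TPM, Lrrc30 at 208 ± 47.0 and 46.3 ± 13.4 TPM, and Amotl2 at 10.7 ± 1.40 and 2.70 ± 0.807 TPM. Bc1, a small non-coding RNA, was at 5.48, 2.59 and 3.10 TPM in control and listed at 0 in radiotherapy muscle. Copies of histone genes are alike in sequence, so the split of reads between them is uncertain.

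Genes as a whole lay lower on the TPM scale in radiotherapy replicates 1 and 2 than in control, and not in replicate 3. The median TPM of the tested genes was 4.59, 4.26 and 7.64 in radiotherapy replicates 1, 2 and 3 and 6.81 to 8.32 in control. The median log2 change over all tested genes was -0.36, with 78.5% of genes below 0, and it was 0.01 with median-of-ratios scaling and -0.02 with quantile normalisation, where 622 and 609 genes were higher and 626 and 780 lower at an unadjusted p under 0.05. In the TPM as deposited, 206 genes were higher and 2299 lower in all 3 radiotherapy libraries than in every control library, 21.0% of those tested against 10% by chance. Other splits of the libraries gave up to 3472 such genes against 2505 for the real split. The 20 most abundant genes took 50.5% and 52.1% of the TPM in radiotherapy replicates 1 and 2, against 30.3% in radiotherapy replicate 3 and 33.0% to 42.6% in control. Mitochondrially encoded genes took 14.6%, 14.8% and 8.57% in the radiotherapy libraries and 11.8%, 7.07% and 13.1% in the control libraries.

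Radiotherapy replicates 1 and 2 were closer to each other than any other pair, with a Spearman correlation of 0.947 and a Pearson correlation of 0.968 across genes, which are not independent replicates. Radiotherapy replicate 3 had Pearson correlations of 0.850 and 0.851 with them and 0.889 to 0.903 with the control libraries (Spearman 0.795 with both and 0.847 to 0.862). The control libraries had Pearson correlations of 0.938 to 0.950 with each other (Spearman 0.909 to 0.927). The principal component with the most variance, 51.7%, put radiotherapy replicates 1 and 2 at 65.4 and 69.5 and radiotherapy replicate 3 at -64.2, with the controls at -36.3 to -8.71. The next component, 21.4% of the variance, put all radiotherapy libraries below 0 and all controls above 0.

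**Figure D3:**
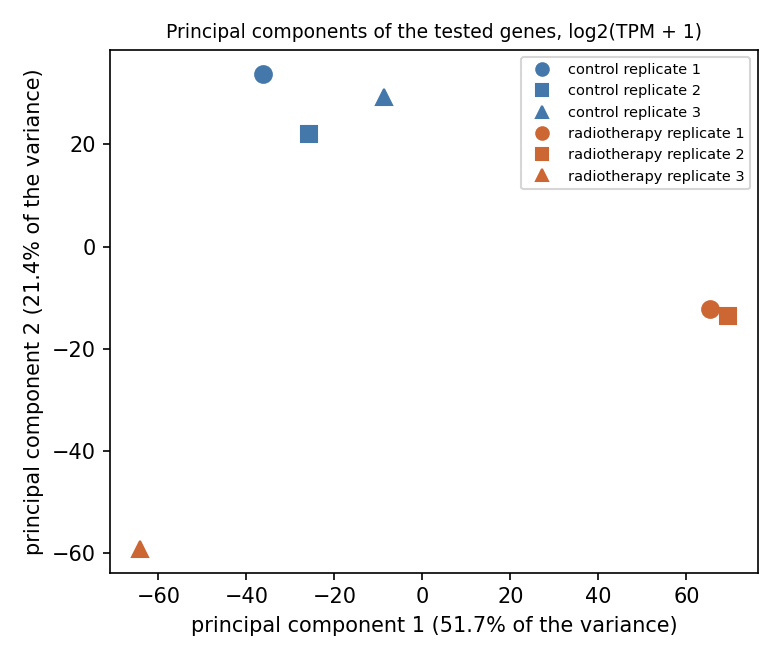
Positions of the 6 libraries on the principal components of the tested genes, log2(TPM + 1), with axis 1 carrying 51.7% and axis 2 carrying 21.4% of the variance. Radiotherapy replicates 1 and 2 lie at 65.4 and 69.5 on axis 1 and replicate 3 at -64.2, and all 3 lie below the controls on axis 2.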

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

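The alternatives reported here were all planned. The cause of each change was not tested, except that leaving out a library leaves fewer samples and a stricter filter fewer genes. Of the 20 lists past the threshold, 6 kept their call and direction under every setting in which they were tested, other than an estimated correlation, fry and leaving out a library. These were matrix, atrophy, p53, immediate early, tendon and adipocyte genes, and 4 of them (matrix, p53, immediate early and tendon) also kept it without each library. Depth is unknown and its limits were not assessed.

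The counts of genes higher and lower, 5 and 2, were 5 and 5 with a pseudocount of 0.1, 4 and 1 with a mean of at least 5 TPM, 3 and 1 with median-of-ratios scaling, 5 and 4 when rescaled without mitochondrial and top genes, and 3 and 1 with quantile normalisation. Without a filter on low values limma called 0 and 0, with 300 and 1996 at an unadjusted p under 0.05. With the replicate block the counts were 4 and 0 for genes, 8 for programme lists and 9 for cell type lists. Jun and the fatty acid oxidation, macrophage and endothelial lists lost their calls with the block. Same-numbered libraries had correlations of deviations of -0.045, -0.112 and -0.201, so not every library correlated best with its own number, and the numbers were not taken as pairs. The counts of programme and cell type lists, 9 and 11, were 5 and 7 with a mean of at least 5 TPM, where tendon, Schwann cell, satellite cell and cell cycle lists had under 5 members left and were not tested. Mitochondrially encoded genes were not tested when rescaled without them. Cell type lists were 4 without a filter, 7 with median-of-ratios scaling and 5 with quantile normalisation. Lists that the filter had left with too few members enter the count without a filter, so those 4 are not all among the 11. Both counts were 0 with an estimated correlation and with fry, which tests whether genes move 1 way and compares no list with other genes. The robust setting has no counterpart in camera and was not run for lists.

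These lists turned direction, none of them past the threshold there (adjusted p). Without a filter they were TGF-beta (0.673), inflammatory (0.327), nuclear-encoded oxidative phosphorylation (0.122) and unfolded protein genes (0.950). With fry they were TGF-beta (0.603), inflammatory (0.800), nuclear-encoded oxidative phosphorylation, lipogenesis and cell cycle (each 0.521), glycolysis (0.480), unfolded protein (0.828), denervation (0.157), progenitor, endothelial and macrophage (each 0.906) and pericyte genes (0.941). With median-of-ratios scaling they were polyamine (0.881), inflammatory (0.132), denervation (0.611) and ribosomal genes (0.0889). Inflammatory genes turned with a pseudocount of 0.1 (0.876), with rescaling (0.662) and with the replicate block (0.933), and ribosomal genes with rescaling (0.919). With quantile normalisation they were inflammatory (0.223), nuclear-encoded oxidative phosphorylation (0.994), denervation (0.679) and fast-fibre genes (0.611). With a mean of at least 5 TPM they were oxidative stress (0.686), denervation (0.693) and ribosomal genes (0.934), and with ranks oxidative stress and ribosomal genes (each 0.948).

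Log2 changes of Tgfb1, Srm, Odc1 and Sat1 were 0.35, 0.24, 0.28 and 0.35 with median-of-ratios scaling and 0.31, 0.22, 0.23 and 0.30 with quantile normalisation. Rescaling gave 0.14, 0.020 and 0.086 for Tgfb1, Odc1 and Sat1, and quantile normalisation gave -0.34 for Myh4.

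Leaving out each library gave 0 to 236 higher and 0 to 3298 lower genes, 6 to 12 programme lists and 5 to 11 cell type lists. Adjusted p ran from 4.41e-10 to 0.955 for interferon, 7.70e-04 to 0.945 for inflammatory, 0.242 to 0.894 for clock, 8.42e-06 to 0.288 for nuclear-encoded oxidative phosphorylation, 0.0893 to 0.967 for lipogenesis, 0.0373 to 0.665 for unfolded protein, 0.0365 to 0.765 for oxidative stress, 0.480 to 0.894 for denervation, 0.0250 to 0.731 for ribosomal, 1.55e-07 to 0.708 for slow-fibre, 0.00218 to 0.905 for macrophage and 1.70e-05 to 0.0588 for neutrophil genes. Log2 changes ran from -0.27 to 1.10 for Ccn2, -0.55 to 0.28 for Tgfb1, -0.88 to 0.24 for Srm, -1.12 to 0.30 for Odc1, -1.45 to 0.62 for Sat1, -0.054 to 0.29 for Myh4 and -0.81 to 1.69 for Myh7.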

Other observations

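All tests in this part, and the choice of histone, acute-phase and immunoglobulin genes, were made after the results were seen.

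Histone genes were counted only after H4c9, H4c8 and H2bc6 had been seen among the lowest p-values, so the count tests nothing, and no enrichment was tested. Of 17 tested histone genes, 13 were lower in all 3 radiotherapy libraries than in every control library, beside 2299 of all 11938 genes, and 0 passed over all genes. H3c11 was at 7.85 ± 0.905 and 2.32 ± 0.346 TPM and H1f4, a linker histone, at 2.92 ± 1.40 and 0.520 ± 0.0265 TPM (SD, n = 3).

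Acute-phase and metallothionein genes set radiotherapy replicate 3 apart from every other library. Saa3, an acute-phase protein, was at 3241 TPM in it, 2.33 and 2.18 TPM in radiotherapy replicates 1 and 2 and 64.2 to 762 TPM in control. Lcn2 was at 4327 TPM against 18.2 and 10.8 TPM and 233 to 554 TPM, and Mt1, a metallothionein, at 14766 TPM against 322 and 620 TPM and 2591 to 5199 TPM. The neutrophil calcium-binding protein S100a8 was at 1141 TPM against 2.74 and 3.95 TPM and 26.3 to 56.1 TPM. Ighm, the IgM heavy chain, was at 44.8 and 28.2 TPM in radiotherapy replicates 1 and 2, 0.60 TPM in replicate 3 and at most 1.48 TPM in control, while Igkc, the kappa light chain, was at 0.14 to 0.54 TPM in all 6.

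Radiotherapy replicate 3 lay nearer to the control libraries than to the other radiotherapy libraries, with a mean Pearson correlation of 0.897 against 0.850. A swap with a control library does not account for this, since 0 control libraries lay nearer to radiotherapy replicates 1 and 2 than to the other controls, nor does blood or neutrophil RNA as the whole cause, since atrophy genes lay 1.34 (SE 0.246) above other genes on the log2 scale in replicate 3 against replicates 1 and 2. A control muscle labelled as radiotherapy stays open: replicate 3 was nearer to the radiotherapy mean in 17.4% of the 3534 genes called without it, against 47.4% (of 19 genes), 21.8% and 16.4% for held-out control replicates 1, 2 and 3. Of features at 0 in 2 controls and at 1 TPM or more in radiotherapy replicates 1 and 2, or the reverse, replicate 3 was like these replicates in 37.7% to 51.6%, and the held-out control in 36.7% to 45.3%, while the Pearson correlations of replicate 3 with the controls, 0.889 to 0.903, lay below those among the controls, 0.938 to 0.950. A different response or illness of that mouse was not tested, and the labels give no group for it.

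Clock genes split the libraries, with Dbp, an output gene of the clock, at 107 and 82.9 TPM in radiotherapy replicates 1 and 2, 1.54 TPM in replicate 3 and 3.71 to 12.3 TPM in control. The mean log2 level of E-box and D-box clock genes minus that of ROR-element clock genes was 1.56, 1.36 and -1.50 in the radiotherapy and -0.64, -1.91 and -0.70 in the control libraries. Another time of day at collection for the radiotherapy mice stays open: the lowest radiotherapy value lay below the highest control value (difference -0.85, control SD 0.718), but this rests on replicate 3 alone, whose label is itself in doubt. No biological explanation was tested.

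The splits of the libraries into 3 and 3 are too few, at 10, for a share under 0.05. A count of genes as large as the real 7 came in 2 of them, the real one included, with a highest other value of 10. For lists with the preset correlation the real count was 20, reached in 3, with a lowest other of 9 and a highest other of 23. For features at 0 in one whole group it was 11, reached in 2, with a highest other of 13. Genes separated between the groups numbered 2505 in the real split and 3472 in the split that puts control replicates 1 and 2 with radiotherapy replicate 3. The highest other counts of called genes, lists and features came from the split that puts control replicate 1 with radiotherapy replicates 1 and 2.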
